A study of Saccharomyces cerevisiae with 61 samples.

How the data were processed

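Total RNA from budding yeast of strain BY4741, released from mating pheromone arrest, was hybridised on 61 two-colour arrays, 16 slides with at most 4 arrays each. Per the labels, the array values come from averaged image files and the submitters' processing notes name limma, without its version. Background correction and normalisation are not given in the sources used here. The deposited values are taken as log2 ratios of Cy5 RNA over Cy3 RNA, since they are signed and centred near 0 on every array. Their sums around the loops varied less than those of independent arrays would, but only slightly less for the untreated loop of wild-type replicate 1 (SD 0.943 against 1.07), where 6 of 15 other sign patterns closed better. The base of the logarithm is not stated and was taken from limma's usual output, so every fold below holds only for base 2. There were 0 missing values, and no background intensities or quality marks are given, so the signal behind each ratio is unknown.

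The table holds 6266 probes. Of these, 5609 carried 1 gene symbol, 0 carried several and 657 carried none. Gene names and locus tags were matched to the reference assembly R64, which found 5608 of the named probes and missed 1. Probes of the same gene were averaged on the log scale (16 genes with several probes, with a mean SD between probes of at most 0.382), and probes without a symbol were kept on their own. This gave 6249 features from 5592 named genes and the unnamed probes.

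Each array title names the Cy5 RNA and then the Cy3 RNA, and dyes followed this order. On 2 wild-type arrays of replicate 1 the title names an MMS sample at 0 min where source name and agent entry give the untreated 0 min sample, and the latter was used. These arrays lie in the MMS and HU loops. On 6 galsicΔP arrays both channels carry the same genotype entry (nrm1Δ on 3 and the parent on 3) although title and source name tell the strains apart, and the title was used. On 1 rad53Δ array the source names give 75 min while title and time entry give 30 min, and 30 min was used. The arrays join 56 RNA extracts (33 wild type, 13 rad53Δ, 10 galsicΔP) in 29 groups, of which 2 hold 1 extract.

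The arrays form loops without a common reference, so the analysis had 2 steps. In step 1, array ratios were turned into relative levels of the extracts by least squares for each feature, within each strain set and with a dye term for each feature. In step 2, limma 3.58.1 in R 4.3.3 was fitted to 54 extracts of all strains together, with terms for the groups and for 14 hybridisation blocks (replicate and time in wild type and rad53Δ, loop in galsicΔP, where each loop joins later parent and nrm1Δ extracts of different replicate numbers). This left 20 residual degrees of freedom, with a prior of 4.41 degrees of freedom and a prior SD of 0.155. The 0 min extracts of wild type and rad53Δ, alone in their blocks, took no part in it. Moderated tests (eBayes without trend) were adjusted by Benjamini-Hochberg over all features within a comparison, at a threshold of 0.05. The median SE of a comparison was 0.082 in wild type, 0.12 in rad53Δ and for nrm1Δ, 0.16 for differences between strains and 0.17 for galsicΔP over time. Labels were read with jsonlite 2.0.0 and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

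Wild-type comparisons average 30, 45, 60 and 75 min, rad53Δ comparisons and the differences between strains 30 and 75 min, and the nrm1Δ comparison 40 and 100 min. Wild-type agents share their untreated samples, so no overlap between agents was counted and MMS was compared with HU by a contrast of its own. Tests at single times, and of 75 min against 45 min for differences within the time course, were added after these.

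Apart from these added tests, the comparisons, tests, 14 gene lists and the rule for named genes were fixed before the data were examined. The lists, from textbook knowledge, are MBF targets (without NRM1 and RAD53), SBF targets, DNA damage inducible genes, histone genes, the CLB2 cluster, M/G1 genes, pheromone response genes, genes of the other mating type, stress-induced genes, proteasome genes, oxidative stress and detoxification genes, amino acid biosynthesis genes, ribosome biogenesis genes and galactose genes, to which ribosomal protein genes were added by symbol. PLM2 and DUN1 stand in both the MBF and the damage-inducible list. Lists were tested with camera at a preset correlation of 0.01, 2-sided, adjusted over the lists within a comparison, and also with the correlation estimated for each list and with fry. MBF and SBF targets were set against each other with camera on their members alone, adjusted over the comparisons. Camera compares moderated t statistics, whereas the values printed beside its p-values are medians of log2 ratios or differences of such medians. Its p-values are thus not tests of the printed medians themselves.

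The rule for named genes took, for each comparison, the 8 largest rises and the 8 largest falls past the threshold with the same sign in each replicate, the member of each list with the largest rise and with the largest fall past the threshold, and in every case NRM1, RAD53, SIC1, RNR1, RNR2, RNR3, RNR4, HUG1, CLN1, CLN2, CDC21, SWI4, CLB5, CLB6, TOS4, PCL1, CLB2, FUS1, GAL1 and the 8 core histone genes. Genes outside it are marked as chosen after their values were seen.

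The procedure was tested on simulated data with 200 changed features among 6249. With noise added at the level of arrays, the share of false calls was 8.39% to 9.26% in wild-type comparisons, above the nominal 5%, and 3.53% to 4.85% in the others. Without array noise it was 3.51% to 6.48% and 3.62% to 7.32%. The simulated extracts varied independently of one another. A deviation shared by the times of 1 replicate was therefore not simulated, and these shares do not cover it. With array noise, changes of 0.5 on the log2 scale were recovered in 89.1% of cases for HU in wild type, 64.2% for HU in rad53Δ, 67.2% for nrm1Δ and 25.4% for the difference between strains in HU.

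Other settings of the processing were tried, 12 of them set in advance: array-level fits without a replicate block (with and without slide as a random term), arrays centred or also scaled, missing values kept, single-probe genes only, a fit per strain set, the array with conflicting times left out, eBayes with trend and robust settings, each replicate left out, camera with estimated correlation, and fry. A further 5 were chosen after seeing the data. Exchanges of treatment labels within blocks were drawn at most 100 times per comparison. Levels of rad53Δ against wild type were left out because no array links these strains, and untreated changes over time were given as values without a test because replicate 2 has no array between times.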

Results

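The series holds 61 two-colour arrays of total RNA from budding yeast of strain BY4741, released from mating pheromone arrest, a step meant to let cells pass through the cycle together. Its title names the question, how DNA replication stress acts on genes of the G1/S transition through the checkpoint kinase Rad53 and the corepressor Nrm1. Of the arrays, 36 compare wild-type RNA (20 in replicate 1, 16 in replicate 2), 15 compare rad53Δ RNA (9 and 6) and 10 compare RNA of a strain the labels call galsicΔP, with or without nrm1Δ (6 in a first loop and 4 in a second). Wild-type cells were sampled without treatment or in 0.2 M hydroxyurea (HU), 0.033% methyl methanesulfonate (MMS) or 50 µM camptothecin (CPT) at 30, 45, 60 and 75 min, with an untreated 0 min sample in replicate 1. The rad53Δ cells were sampled at 30 and 75 min without treatment or in HU or MMS, with an untreated 0 min sample in replicate 1, and the galsicΔP cells at 0, 40 and 100 min without treatment. The arrays join 56 RNA extracts in 29 groups of at most 2 extracts, and this small number limits the precision. Median values of the arrays lay between -0.0258 and 0.0249 on the deposited log scale, whose base is not given and was taken as 2. The labels do not say that replicates came from separate cultures, so every p-value below measures only the spread between these samples. In means over several times, each time of a replicate counts as a separate sample. A deviation shared by the times of 1 replicate is thus treated as independent at each time. The SE and p-value of such means can therefore be too small. Values are log2 ratios ± SE, from n = 2 replicates at each time unless stated otherwise. For an agent, rose and fell mean higher and lower than in untreated samples of the same time. Cell cycle genes of those untreated samples changed over time themselves. The SE of a gene comes from 1 spread shared by all strains, so it does not show the scatter within a strain or agent. Where the members behind a small count are listed by name, those outside the rule for named genes were chosen after their values were seen.

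The course of cell cycle genes in untreated wild-type cells can be followed in replicate 1 alone and is given as values without a test. Targets of MBF, the factor that drives DNA synthesis genes late in G1, had a median of 1.60 above the 0 min sample at 30 min, 0.55 at 45 min, 0.05 at 60 min and 0.73 at 75 min. Targets of SBF, the sister factor that drives G1 cyclins and cell wall genes, stood at 1.77, 1.16, 0.32 and 0.52 at these times. Histone genes, transcribed in S phase, stood at 3.29, 3.09, 1.39 and 0.88. The CLB2 cluster, which acts from G2 to mitosis, stood at -0.08, 0.78, 1.83 and 1.58, and pheromone response genes at -1.85, -2.16, -2.09 and -1.93.

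HU, an inhibitor of ribonucleotide reductase, was set against no treatment to ask which transcripts change when replication forks run short of nucleotides. HUG1 (YML058W-A), a checkpoint-induced inhibitor of ribonucleotide reductase, rose 14.8-fold (3.88 ± 0.33 over the 4 times, limma adjusted p = 5.2e-09). The reductase subunit genes RNR2 (YJL026W), RNR4 (YGR180C) and RNR3 (YIL066C) rose by 2.24 ± 0.17, 2.06 ± 0.10 and 1.76 ± 0.15, and DDR2 (YOL052C-A), a general stress gene, by 1.81 ± 0.13. Of 19 genes known to be induced by DNA damage, 16 rose and 1, the haspin kinase gene ALK1 at -0.77, fell (median 0.53, adjusted p = 1.6e-12, the same counts adjusted over the list alone). Of 36 MBF targets, 28 rose and 0 fell (28 and 0 adjusted over the list alone). The MBF median was 0.49 (adjusted p = 1.1e-10, adjusted p = 0.21 with an estimated correlation). Examples are the thymidylate synthase gene CDC21 (YOR074C) at 0.84 ± 0.18, the transcription factor gene SWI4 (YER111C) at 0.57 ± 0.15 and the S-phase cyclin gene CLB6 (YGR109C) at 0.70 ± 0.20. Of 29 SBF targets, 2 rose, SWE1 and ELO1, and 2 fell, YOX1 and NDD1 (the same counts adjusted over the list alone). The SBF median was 0.02 (adjusted p = 0.87). The G1 cyclin gene CLN2 (YPL256C), an SBF target, stood at -0.28 ± 0.21 (adjusted p = 0.34). Against each other, MBF targets lay 0.47 above SBF targets (adjusted p = 2.9e-09, adjusted p = 0.2 with an estimated correlation). NRM1 (YNR009W) itself stood at 0.31 ± 0.13 (adjusted p = 0.075) over the 4 times and was higher at 75 min, by 1.04 ± 0.26 (adjusted p = 0.0063).

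Genes of later cycle phases stood lower in HU than in untreated cells of the same times. In the CLB2 cluster 18 of 19 members fell and 0 rose (18 adjusted over the list alone), among them the cytokinesis gene HOF1 (YMR032W) at -1.58 ± 0.21, the transcription factor gene SWI5 (YDR146C) at -1.55 ± 0.21 and the mitotic cyclin gene CLB2 (YPR119W) at -1.05 ± 0.18. The CLB2 cluster median was -0.83 (adjusted p = 2.1e-13, adjusted p = 0.063 with an estimated correlation). Against the 0 min sample of replicate 1, the cluster median went from -0.33 at 30 min to 0.33 at 75 min in HU. Without treatment it went from -0.08 to 1.58, so the cluster rose less in HU there. Of 21 M/G1 genes, 13 fell (14 adjusted over the list alone), with the cell wall gene PIR1 (YKL164C) at -1.52 ± 0.15. The M/G1 median was -0.31 (adjusted p = 3e-08, adjusted p = 0.1 with an estimated correlation). Of 30 stress-induced genes, 23 rose (25 adjusted over the list alone), such as the trehalose synthase gene TSL1 (YML100W) at 1.60 ± 0.17. The stress list median was 0.68 (adjusted p = 5.3e-17). Of 29 oxidative stress and detoxification genes, 19 rose and 1, the exporter gene PDR5, fell (20 and 1 adjusted over the list alone). The detoxification list median was 0.49 (adjusted p = 1.1e-10). Of 34 proteasome genes, 28 rose (29 adjusted over the list alone). The proteasome median was 0.33 (adjusted p = 4.5e-12, adjusted p = 0.063 with an estimated correlation). Of 51 ribosome biogenesis genes, 44 fell (46 adjusted over the list alone), the RNA helicase gene DBP2 (YNL112W) by most, at -1.01 ± 0.11. The ribosome biogenesis median was -0.40 (adjusted p = 4.2e-19, adjusted p = 0.062 with an estimated correlation). Of 129 ribosomal protein genes 14 fell (8 adjusted over the list alone; median -0.06, adjusted p = 0.047, adjusted p = 0.65 with an estimated correlation), a call that ended without wild-type replicate 2, where the median was -0.01. No shift passed for the amino acid list (median 0.05), the pheromone list (-0.01), the galactose list (0.05) or the 5 genes of the other mating type (0.22), with adjusted p from 0.31 to 0.6.

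In total, 2067 of 6249 features passed in HU, 986 higher and 1081 lower, and 63 of these changed by more than 2-fold. With 1 value per replicate and treatment in place of a value per time, 843 passed. Across all features the responses of the 2 replicates correlated at r = 0.68, where features are not independent of one another.

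MMS, which methylates DNA, was compared with no treatment in the same way, and its largest rises were those of detoxification genes. The sulfite pump gene SSU1 (YPL092W) rose 23.8-fold (4.57 ± 0.10, adjusted p = 1.5e-21), the drug exporter gene FLR1 (YBR008C) by 4.03 ± 0.15, the sulfiredoxin gene SRX1 (YKL086W) by 3.90 ± 0.20 and the flavohaemoglobin gene YHB1 (YGR234W) by 3.87 ± 0.15. Of 29 oxidative stress and detoxification genes, 26 rose and 1, PDR5, fell (27 and 1 adjusted over the list alone). The detoxification list median was 1.52 (adjusted p = 9e-19). Of 34 proteasome genes, 33 rose (34 adjusted over the list alone), led by the ATPase subunit gene RPT2 (YDL007W) at 1.55 ± 0.07. The proteasome median was 1.09 (adjusted p = 2e-22). Of 19 damage-inducible genes, 17 rose and 1, ALK1, fell (the same adjusted over the list alone), the former including HUG1 at 2.36 ± 0.33, RNR3 at 1.95 ± 0.15, RNR4 at 1.53 ± 0.10 and RNR2 at 1.53 ± 0.17. The damage median was 1.204 (adjusted p = 1.8e-09). Of 30 stress-induced genes 27 rose (27 adjusted over the list alone; median 0.96, adjusted p = 4e-12).

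Of 36 MBF targets, 33 rose in MMS and 0 fell (33 adjusted over the list alone). The MBF median was 0.69 (adjusted p = 4.6e-09, adjusted p = 0.24 with an estimated correlation). CDC21 rose by 1.53 ± 0.18, CLB6 by 1.28 ± 0.20 and TOS4 (YLR183C), a transcription factor gene, by 1.56 ± 0.29. RNR1 (YER070W), the large reductase subunit gene, had 3.42 ± 0.54, with 5.44 in replicate 1 and 1.39 in replicate 2, so its size is uncertain. Of 29 SBF targets 7 rose and 5 fell, HO, MSB2, PCL2, YOX1 and NDD1 (6 and 5 adjusted over the list alone). The SBF median was 0.22 (adjusted p = 0.64), and MBF targets lay 0.47 above SBF targets (adjusted p = 1.1e-07, adjusted p = 0.21 with an estimated correlation). NRM1 stood at -0.09 ± 0.26 at 30 min and rose by 1.39 ± 0.26 at 75 min (adjusted p = 0.00014). Its 4-time mean of 0.39 ± 0.13 (adjusted p = 0.013) no longer passed without wild-type replicate 1, at 0.10, or with arrays scaled to equal spread, at 0.34 (adjusted p = 0.26). In the CLB2 cluster 18 of 19 members fell (18 adjusted over the list alone), with SWI5 at -2.07 ± 0.21 and CLB2 at -1.56 ± 0.18. The CLB2 cluster median was -1.17 (adjusted p = 1.4e-08, adjusted p = 0.18 with an estimated correlation). Of 21 M/G1 genes 13 fell and 1, PIR3, rose (the same adjusted over the list alone), the former including the Cdk inhibitor gene SIC1 (YLR079W) at -0.59 ± 0.16. The M/G1 median was -0.59 (adjusted p = 0.00015, adjusted p = 0.24 with an estimated correlation). Of 27 pheromone response genes 21 fell and 1, PRM5, rose (the same adjusted over the list alone). The pheromone median was -0.39 (adjusted p = 0.00018, adjusted p = 0.24 with an estimated correlation).

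Growth-related lists moved in opposite directions in MMS. Of 43 amino acid biosynthesis genes 27 rose and 5 fell (28 and 5 adjusted over the list alone). The arginine gene ARG1 (YOL058W) stood at 2.66 ± 0.15, and the genes that fell were ILV1, ILV3, ARG8, GLN1 and the methionine synthase gene MET6 (YER091C), the last at -0.91 ± 0.14. The amino acid list median was 0.57 (adjusted p = 4.8e-07, adjusted p = 0.24 with an estimated correlation). Of 51 ribosome biogenesis genes 49 fell (49 adjusted over the list alone; median -0.76, adjusted p = 2.2e-19). Of 129 ribosomal protein genes 45 fell and 3, RPL10, RPS25A and RPS26A, rose (42 and 3 adjusted over the list alone; median -0.13, adjusted p = 0.0015, adjusted p = 0.46 with an estimated correlation), a call that ended without wild-type replicate 2, where the median was -0.07. The acid phosphatase gene PHO3 (YBR092C) fell by 2.50 on the log2 scale and COX1 (Q0045), encoded in the mitochondrial genome, by 2.07. In total 3634 features passed, 1747 higher and 1887 lower, with 338 beyond 2-fold and a correlation between replicates of r = 0.85 across features, which are not independent.

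HU and MMS were also compared with each other, directly on arrays in replicate 2 and through the shared 0 min sample in replicate 1, to ask where the agents differ. FLR1, SSU1 and the multidrug exporter gene ATR1 (YML116W) stood 3.87 ± 0.15, 3.41 ± 0.10 and 2.92 ± 0.08 higher in MMS, whereas HUG1, RNR2 and RNR4 stood at -1.52 ± 0.33, -0.72 ± 0.17 and -0.52 ± 0.10, lower than in HU (adjusted p = 0.00066, 0.0013 and 0.00015). The difference of RNR2 no longer passed without wild-type replicate 1 (-0.48, adjusted p = 0.21). Higher in MMS were 28 of 29 oxidative stress genes (1, PDR5, lower, the same adjusted over the list alone; median 0.74, adjusted p = 4.7e-22) and 33 of 34 proteasome genes (33 adjusted over the list alone; median 0.72, adjusted p = 2e-27). Of 19 damage-inducible genes 7 were higher in MMS, among them the polyubiquitin gene UBI4 (YLL039C) at 1.48 ± 0.09, and 3, those named above, lower (8 and 3 adjusted over the list alone; median 0.19, adjusted p = 0.013, adjusted p = 0.23 with an estimated correlation). Amino acid genes were higher in 26 of 43 cases and lower in 3, MET6, GLN1 and ILV1 (27 and 3 adjusted over the list alone). The amino acid median was 0.45 (adjusted p = 7.3e-10, adjusted p = 0.23 with an estimated correlation). Ribosome biogenesis genes were lower in 37 of 51 cases (40 adjusted over the list alone). The ribosome biogenesis median was -0.36 (adjusted p = 3.5e-12, adjusted p = 0.23 with an estimated correlation). Pheromone response genes were lower in 17 of 27 cases and higher in 1, PRM5 (18 and 1 adjusted over the list alone). The pheromone median was -0.36 (adjusted p = 7.6e-06, adjusted p = 0.23 with an estimated correlation). MBF targets were higher in 11 of 36 cases (11 adjusted over the list alone). The MBF median was 0.24 (adjusted p = 0.0034, adjusted p = 0.67 with an estimated correlation). They lay 0.17 above SBF targets (adjusted p = 0.026, adjusted p = 0.68 with an estimated correlation), and 0.04 without wild-type replicate 1 (adjusted p = 0.11) or 0.15 with scaled arrays (adjusted p = 0.068). The haem protein genes CYC1 (YJR048W) and CYB5 (YNL111C) stood at -2.13 ± 0.13 and -1.78 ± 0.12. In total 2572 features differed, 1281 higher and 1291 lower in MMS, and 1229 with 1 value per replicate and treatment.

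CPT, an inhibitor of topoisomerase I, was compared with no treatment to ask which genes respond to a further kind of fork damage. The factor gene PLM2 (YDR501W) rose by 1.06 ± 0.13, RNR4 by 0.98 ± 0.10, DDR2 by 0.96 ± 0.13 and RNR2 by 0.99 ± 0.17. HUG1 averaged 1.17 ± 0.33 (adjusted p = 0.037), but from 0.33 in replicate 1 and 2.01 in replicate 2, and it no longer passed without replicate 2. Of 19 damage-inducible genes 11 rose and 0 fell (12 adjusted over the list alone; median 0.32, adjusted p = 1.6e-11). Among the 36 MBF targets 5 rose (9 adjusted over the list alone), PLM2, DUN1 (YDL101C) at 0.79 ± 0.13, CDC21 at 0.67 ± 0.18, RFA2 (YNL312W) at 0.44 ± 0.11 and CDC45 (YLR103C) at 0.50 ± 0.15. The MBF median was 0.22 (adjusted p = 5.3e-07, adjusted p = 0.5 with an estimated correlation), with a difference to SBF targets of 0.27 (adjusted p = 9.4e-05, adjusted p = 0.32 with an estimated correlation). The SBF targets did not pass (1 rose of 29, the polarity gene GIC1; median -0.05, with a test that leaned upward, adjusted p = 0.94). Of 21 M/G1 genes 9 fell (10 adjusted over the list alone), with the daughter-cell gene DSE4 (YNR067C) at -0.73 ± 0.12. The M/G1 median was -0.28 (adjusted p = 9.7e-06, adjusted p = 0.48 with an estimated correlation). Stress-induced genes had a median of 0.19 (4 rose of 30, DDR2, PGM2, HSP78 and GRE3; 8 adjusted over the list alone; adjusted p = 4.7e-05, adjusted p = 0.48 with an estimated correlation). Without wild-type replicate 2 it was 0.00 (adjusted p = 1).

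Of 6249 features 376 passed in CPT, 155 higher and 221 lower, and the replicates correlated at r = 0.04 across features. That count was 110 without wild-type replicate 1, 1976 without replicate 2 and 59 in a fit of the wild-type arrays alone. The array-level fits turned the balance, with 184 higher and 98 lower, where 140 of the 376 were kept, and with slide as a random term 223 higher and 128 lower. With 1 value per replicate and treatment, 5 passed: RNR4, DDR2, the checkpoint kinase gene DUN1 at 0.79, the daughter-cell gene DSE3 (YOR264W) at -0.72 and an unannotated probe, A_06_P2728, at 1.04, the last 3 chosen after their values were seen. Single times gave 0 features at 30 min and 0 at 45 min in limma, where 579 and 309 had an unadjusted p under 0.05, then 26 at 60 min and 58 at 75 min. Other exchanges of the CPT and untreated labels gave up to 1236 features.

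Time resolved the wild-type responses further. Relative to untreated cells of the same time, 8 of 10 histone genes stood lower in HU at 45 min (median -1.31) and 7 higher at 75 min (median 1.05). In MMS 8 stood lower at 45 min (median -1.06) and 7 higher at 75 min (median 1.12). The change between these times passed as a test of its own in HU (2.38, adjusted p = 4.9e-28) and in MMS (2.25, adjusted p = 2.2e-17), and in CPT at 0.23 (adjusted p = 0.023, adjusted p = 0.63 with an estimated correlation). In replicate 1, histone medians above 0 min were 1.98 at 45 min and 1.89 at 75 min in HU. In MMS they were 2.30 and 2.11. Untreated cells went from 3.09 to 0.88, so there the change came mainly from the untreated samples, as values without a test. The untreated 45 min sample of replicate 2, in doubt as described below, also enters the tests between times. Averaged over the 4 times, the opposite differences from untreated cells left histone medians of -0.20 in HU and -0.22 in MMS. Neither passed (adjusted p = 0.11 and 0.77). Over 60 and 75 min alone, a choice made after seeing the data, the medians turned to 0.60 and 0.63. MBF targets in HU had medians of 0.98 at 30 min, 0.23 at 45 min, 0.95 at 60 min and -0.09 at 75 min, and in MMS 0.96, 0.50, 1.06 and 0.31. In CPT they were 0.85, -0.003, 0.705 and -0.35, the last below 0 in both replicates (-0.34 and -0.68; adjusted p = 1.4e-05, adjusted p = 0.55 with an estimated correlation). Set against SBF targets with camera, MBF targets did not pass at 75 min in HU (0.205, adjusted p = 0.078), MMS (0.157, 0.078) or CPT (0.23, 0.63). Nor did they in CPT at 45 min (0.065, 0.14). They passed at the other wild-type times, but at none with an estimated correlation. In HU 18 features passed at 30 min and 1230 at 75 min, and in MMS 697 and 2635. Tests at single times and between times were chosen after the comparisons above.

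**Figure D1:**
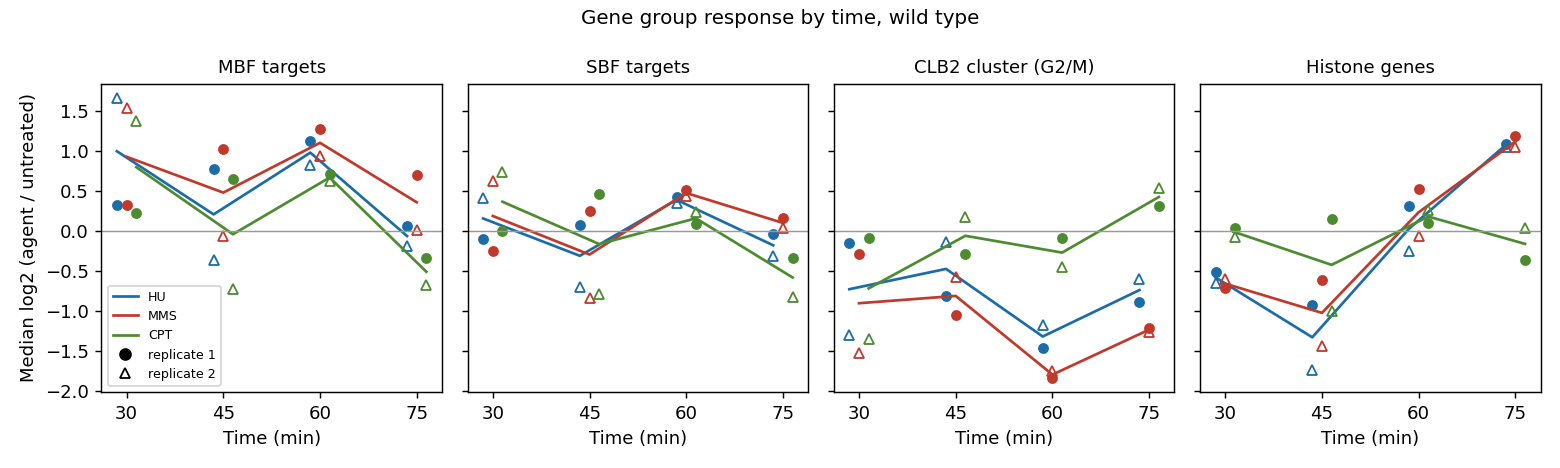
Median log2 ratio of agent over untreated (vertical axis) against time in minutes (horizontal axis) for 4 gene lists in wild-type cells, with filled circles for replicate 1, open triangles for replicate 2 and lines through the mean of both for HU, MMS and CPT. MBF medians at 30 min in HU were 0.33 in replicate 1 and 1.67 in replicate 2, while histone genes in HU and MMS turned from below 0 at 45 min to above 0 at 75 min in both replicates.

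In HU and MMS the replicates were less alike at the early times, with r across features for HU of 0.19 at 30 min, 0.39 at 45 min, 0.55 at 60 min and 0.7 at 75 min, and for MMS of 0.45, 0.7, 0.83 and 0.85. In CPT r was 0.18, -0.27, 0.28 and 0.12 at these times, with no such course. For MBF targets the HU median at 30 min was 0.33 in replicate 1 and 1.67 in replicate 2, and at 45 min 0.78 and -0.36. Over 115 cell cycle genes the responses of replicate 2 at 30 min matched those of replicate 1 best when the latter were computed against the untreated 45 min sample (r = 0.95, against 0.47 for 30 min), and those at 45 min matched best against the untreated 30 min sample (0.58, against 0.02). The labels were kept as given. An exchange of these untreated samples would leave the size of every mean over the 4 times as it is. It would change the values at 30 and 45 min and the tests of 75 min against 45 min. The differences between rad53Δ and wild type that include 30 min would change too. Through the spread that all strains share in the fit, SEs, p-values and counts of every comparison could also change.

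In the strain without RAD53 (YPL153C), the probe of this gene varied little. Its log ratios lay between -0.28 and 0.06 on the 15 rad53Δ arrays and between -1.85 and 2.31 on the 36 wild-type arrays, where RAD53 is itself a cell cycle gene. Since no array sets rad53Δ against wild type, the level of the deleted gene cannot be compared directly.

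To ask what MMS does without Rad53, rad53Δ cells in MMS were compared with untreated ones, and the detoxification and proteasome genes rose. SSU1 rose by 3.59 ± 0.14, YHB1 by 3.50 ± 0.21, SRX1 by 3.36 ± 0.28 and the glutathione peroxidase gene GPX2 (YBR244W) by 2.33 ± 0.16, as means of 30 and 75 min. Of 29 oxidative stress genes 23 rose and 1, PDR5, fell (the same adjusted over the list alone; median 0.89, adjusted p = 3e-25), and of 34 proteasome genes 32 rose (33 adjusted over the list alone; median 0.64, adjusted p = 1.4e-32). Of 19 damage-inducible genes 5 rose (6 and 1 lower adjusted over the list alone). The damage median was 0.19 (adjusted p = 0.0069, adjusted p = 0.21 with an estimated correlation). The 5 are UBI4 at 1.39 ± 0.13, DDI1 (YER143W) at 0.99 ± 0.13, DDR48 (YMR173W) at 0.99 ± 0.14, RAD23 (YEL037C) at 0.44 ± 0.11 and MAG1 (YER142C) at 0.38 ± 0.12. The checkpoint targets HUG1, RNR2, RNR3 and RNR4 stood at -0.65 ± 0.47, -0.40 ± 0.24, -0.11 ± 0.22 and -0.37 ± 0.14, none of which passed with the spread shared by all strains. Of 36 MBF targets 2 rose and 0 fell (0 adjusted over the list alone), namely POL30 (YBR088C) at 0.92 ± 0.30 and RFA2 at 0.49 ± 0.15. The MBF median was 0.15 (adjusted p = 0.11), and MBF and SBF targets differed by 0.10 (adjusted p = 0.3). Ribosomal protein genes had a median of -0.19, with 26 of 129 lower (34 adjusted over the list alone; adjusted p = 4.9e-12, adjusted p = 0.21 with an estimated correlation). Of 43 amino acid genes 13 rose and 1, GLN1, fell (15 and 2 adjusted over the list alone). The amino acid median was 0.15 (adjusted p = 0.0028, adjusted p = 0.75 with an estimated correlation). Of 21 M/G1 genes 9 fell and 1, PIR3, rose (the same adjusted over the list alone). The M/G1 median was -0.30 (adjusted p = 2e-07, adjusted p = 0.21 with an estimated correlation). In total 836 features passed, 537 higher and 299 lower, with 203 without rad53Δ replicate 1, 168 without replicate 2 and 2396 in a fit of the rad53Δ arrays alone.

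In rad53Δ cells HU was compared with no treatment to ask which part of its effect remains without the kinase. The transporter gene YHK8 (YHR048W) rose by 1.57 ± 0.17 and the meiotic recombination gene REC104 (YHR157W) by 1.47 ± 0.09, while the membrane protein gene MRH1 (YDR033W) fell by 2.08 on the log2 scale and PHO3 by 1.88. HUG1 stood at 0.12 ± 0.47, RNR2 at 0.63 ± 0.24, RNR3 at 0.14 ± 0.22 and RNR4 at 0.30 ± 0.14, none of which passed with the spread shared by all strains. More features passed in a fit of the rad53Δ arrays alone, as given below, so the lack of a call here does not exclude smaller changes. Of 19 damage-inducible genes 1 rose, DDR48 at 0.78 ± 0.14 (1 adjusted over the list alone; median 0.13, adjusted p = 0.018, adjusted p = 0.36 with an estimated correlation). None of the 36 MBF targets (0 rose, 0 fell) passed in limma, over all features and adjusted over the list alone, where 3 had an unadjusted p under 0.05 (median 0.17, adjusted p = 0.03, adjusted p = 0.62 with an estimated correlation). The difference between MBF and SBF targets was 0.02 (adjusted p = 0.057), and 0.16 (adjusted p = 0.0028) without rad53Δ replicate 1. By time it was 0.36 at 30 min (adjusted p = 3.8e-05, adjusted p = 0.29 with an estimated correlation) and -0.11 at 75 min (adjusted p = 0.91). In the CLB2 cluster 3 of 19 members fell (16 adjusted over the list alone), namely CHS2 (YBR038W) at -1.07 ± 0.24, KIN3 (YAR018C) at -0.98 ± 0.23 and TEM1 (YML064C) at -0.32 ± 0.09. The CLB2 cluster median was -0.56 (adjusted p = 1.1e-09, adjusted p = 0.36 with an estimated correlation). Of 30 stress-induced genes 7 rose and 1, YGP1, fell (14 and 1 adjusted over the list alone). The stress list median was 0.39 (adjusted p = 1.1e-07, adjusted p = 0.36 with an estimated correlation). Of 21 M/G1 genes 6 fell and 1, DSE1, rose (10 and 1 adjusted over the list alone). The M/G1 median was -0.34 (adjusted p = 5.8e-05, adjusted p = 0.36 with an estimated correlation). In total 447 features passed, 248 higher and 199 lower, with 43 without rad53Δ replicate 1, 34 without replicate 2 and 2003 in a fit of the rad53Δ arrays alone. At 30 min alone 1 feature passed, YHK8 at 1.49, and at 75 min 1021.

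Whether the 2 strains responded differently was tested as the rad53Δ response minus the wild-type response over 30 and 75 min, which none of the arrays measures directly. For MMS, DDR2 stood at -2.79 ± 0.26 (adjusted p = 4.1e-07), RNR4 at -1.77 ± 0.20, RNR3 at -1.82 ± 0.31 and the phosphoglucomutase gene PGM2 (YMR105C) at -1.95 ± 0.21. In wild type the MMS responses of these genes over the same times were 2.25, 1.4, 1.71 and 1.93, and in rad53Δ -0.55, -0.37, -0.11 and -0.02. For HU, RNR4 stood at -1.49 ± 0.20 (adjusted p = 8.7e-05), from 1.79 in wild type and 0.30 in rad53Δ. HUG1 stood at -3.00 ± 0.66 for HU (adjusted p = 0.013), from 3.12 and 0.12, and at -2.36 ± 0.66 for MMS (adjusted p = 0.028). The differences of HUG1 no longer passed when either rad53Δ replicate was left out (adjusted p from 0.19 to 0.27) or the arrays were scaled to equal spread (0.073 and 0.23). RNR2 stood at -1.28 ± 0.33 for HU and -1.67 ± 0.33 for MMS, which likewise no longer passed without either rad53Δ replicate (adjusted p from 0.074 to 0.38).

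As groups, the damage-inducible genes responded less in rad53Δ cells to HU (7 of 19 lower, 9 adjusted over the list alone; median -0.34, adjusted p = 5.7e-09) and to MMS (10 lower, 13 adjusted over the list alone; median -0.57, adjusted p = 5.3e-12). Stress-induced genes responded less to MMS in 20 of 30 cases (24 adjusted over the list alone; median -0.81, adjusted p = 2.4e-25) and to HU in 5 (8 adjusted over the list alone; median -0.44, adjusted p = 1.4e-10, adjusted p = 0.11 with an estimated correlation), the 5 being DDR2 at -1.50 ± 0.26, PGM2 at -1.30 ± 0.21, YGP1 (YNL160W) at -1.54 ± 0.35, MSC1 (YML128C) at -1.38 ± 0.28 and SOL4 (YGR248W) at -0.79 ± 0.20. Oxidative stress genes responded less to MMS in 12 of 29 cases (14 adjusted over the list alone; median -0.50, adjusted p = 5.1e-11). Ribosome biogenesis genes, lower in wild-type MMS, were relatively higher in rad53Δ in 32 of 51 cases (44 adjusted over the list alone). The ribosome biogenesis median was 0.61 (adjusted p = 3.8e-27). Of 21 M/G1 genes 9 were higher for HU (11 adjusted over the list alone; median 0.73, adjusted p = 2.4e-09, adjusted p = 0.12 with an estimated correlation), such as DSE3 at 1.39 ± 0.17 and DSE1 (YER124C) at 1.34 ± 0.21, and 8 for MMS (11 adjusted over the list alone; median 0.65, adjusted p = 3e-06, adjusted p = 0.2 with an estimated correlation).

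MBF targets had a lower median response in rad53Δ cells, -0.26 for HU (2 of 36 lower, 2 adjusted over the list alone; adjusted p = 6.7e-05, adjusted p = 0.57 with an estimated correlation) and -0.48 for MMS (4 lower, 8 adjusted over the list alone; adjusted p = 8.9e-09, adjusted p = 0.23 with an estimated correlation). The members are PLM2 at -1.28 ± 0.26 and DUN1 at -1.22 ± 0.25 for HU and RNR1 at -4.09 ± 1.09 (-6.35 and -1.83 in the replicates), PLM2 at -1.67 ± 0.26, DUN1 at -1.31 ± 0.25 and RFA2 at -0.83 ± 0.21 for MMS. PLM2 and DUN1 also stand in the damage-inducible list, so for HU no MBF member outside that list passed. Relative to SBF targets they lay at -0.31 (adjusted p = 0.00011, adjusted p = 0.32 with an estimated correlation) and -0.48 (adjusted p = 1.4e-05, adjusted p = 0.32 with an estimated correlation). The MBF median for HU rested on wild-type replicate 2, without which it was 0.01. At 30 min the medians were -0.17 and -1.55 in replicates 1 and 2 for HU and -0.37 and -1.55 for MMS. The untreated wild-type sample of replicate 2 at that time is in doubt, as described above. At 75 min alone the medians turned to 0.27 for HU (adjusted p = 0.46) and 0.03 for MMS (adjusted p = 0.42). Untreated MBF targets of replicate 1 stood 0.73 above 0 min in wild type at 75 min and 0.14 in rad53Δ, values without a test. Each rests on a single extract set against its own 0 min sample, and the wild-type one lies in the untreated loop that closed poorly. Whether the untreated baselines of the strains differed at 75 min therefore stays open. NRM1 at 75 min differed by -1.22 ± 0.37 for HU (adjusted p = 0.042) and -1.34 ± 0.37 for MMS (adjusted p = 0.02), from -0.19 and 0.05 in rad53Δ cells. In total 175 features differed for HU, 88 higher and 87 lower, and 460 for MMS, 245 higher and 215 lower, with 54 and 294 from 1 value per replicate and treatment. Without rad53Δ replicate 1 these counts were 36 and 45, without rad53Δ replicate 2 they were 16 and 88, and with scaled arrays 98 and 149. At 30 min 0 features passed for HU in limma, where 266 had an unadjusted p under 0.05, and 19 for MMS.

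**Figure D2:**
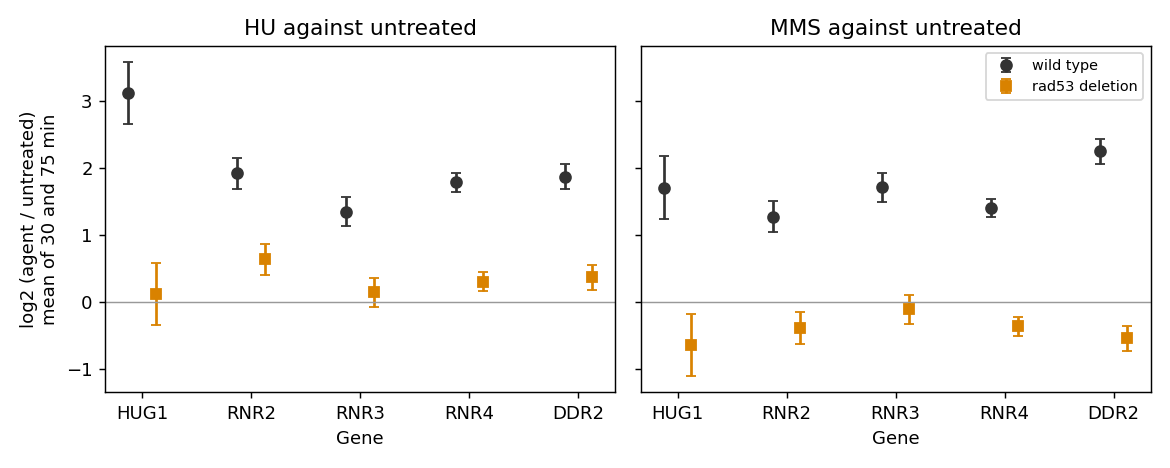
Log2 ratio of agent over untreated as the mean of 30 and 75 min (vertical axis) for 5 genes (horizontal axis), HU on the left and MMS on the right, with circles for wild type and squares for rad53Δ (n = 2 replicates at each time). Bars are 1 SE from the spread that all strains share in the fit, so they do not show the scatter within a strain. RNR4 stood at 1.79 in wild type and 0.30 in rad53Δ in HU, and at 1.4 and -0.37 in MMS.

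The effect of the corepressor Nrm1 was tested in untreated galsicΔP cells at 40 and 100 min. NRM1 itself stood at -4.17 ± 0.19 in the nrm1Δ strain (adjusted p = 5.9e-14), -3.52 at 40 min and -4.81 at 100 min. Of 36 MBF targets 31 rose and 0 fell without Nrm1 (34 adjusted over the list alone). The MBF median was 0.81 (adjusted p = 5.6e-14, adjusted p = 0.22 with an estimated correlation). The S-phase cyclin gene CLB5 (YPR120C) rose by 1.55 ± 0.15, the cohesin gene MCD1 (YDL003W) by 1.72 ± 0.27, the sliding clamp gene POL30 (YBR088C) by 1.65 ± 0.30 and CDC21 by 1.16 ± 0.26. RNR1 stood at 1.65 ± 0.77 (adjusted p = 0.1). Of 29 SBF targets 22 rose and 0 fell (23 adjusted over the list alone), including CLN2 at 0.96 ± 0.30 (adjusted p = 0.015). The SBF median was 0.73 (adjusted p = 7.2e-09, adjusted p = 0.22 with an estimated correlation). MBF and SBF targets differed by 0.08 (adjusted p = 0.15), which turned to -0.23 (adjusted p = 0.44) and -0.19 (adjusted p = 0.36) in the array-level fits and to -0.11 with scaled arrays (adjusted p = 0.93). The loops disagreed on SBF targets, with medians of 0.38 in the first and 1.26 in the second, against 0.80 and 0.80 for MBF targets. At 40 and 100 min the first loop holds replicate 1 of the parent and replicate 2 of nrm1Δ and the second the reverse, so loop and replicate cannot be separated here. Without the first loop the difference between MBF and SBF targets was -0.45 (adjusted p = 0.0032) and without the second 0.42 (adjusted p = 1.7e-05). By time, MBF targets lay -0.27 from SBF targets at 40 min (adjusted p = 0.97) and 0.27 above them at 100 min (adjusted p = 0.0032, adjusted p = 0.56 with an estimated correlation).

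**Figure D3:**
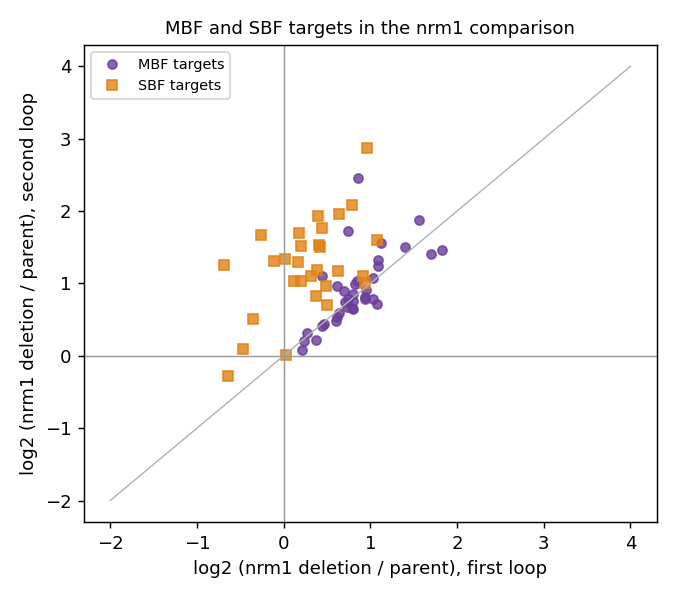
Log2 ratio of nrm1Δ over its parent for each member of the MBF list (circles) and the SBF list (squares), the first loop of arrays on the horizontal axis and the second on the vertical axis, with a diagonal line where both are equal. MBF targets lie on both sides of the line, with medians of 0.80 and 0.80 and with RNR1, TOS4 and POL1 well above it. SBF targets other than CDC10 lie above it, with list medians of 0.38 and 1.26.

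Outside the G1/S lists, mating and stress genes fell in nrm1Δ cells. Of 27 pheromone response genes 22 fell and 0 rose (22 and 2 adjusted over the list alone), among them the pheromone genes MFA2 (YNL145W) at -2.26 ± 0.18 and MFA1 (YDR461W) at -2.18 ± 0.18. The pheromone median was -0.75 (adjusted p = 5.6e-14, adjusted p = 0.11 with an estimated correlation). Of 30 stress-induced genes 24 fell (25 adjusted over the list alone), with the glycogen phosphorylase gene GPH1 (YPR160W) at -2.41 ± 0.22. The stress list median was -0.77 (adjusted p = 5.8e-11, adjusted p = 0.11 with an estimated correlation). Of 43 amino acid genes 24 fell and 3, LYS1, LYS9 and LYS20, rose (27 and 5 adjusted over the list alone; median -0.40, in the loops -0.66 and -0.20; adjusted p = 3.1e-06, adjusted p = 0.33 with an estimated correlation), of 13 galactose genes 11 fell (11 adjusted over the list alone; median -0.48, in the loops -0.715 and -0.35; adjusted p = 3.9e-06, adjusted p = 0.11 with an estimated correlation) and of 21 M/G1 genes 12 fell and 1, DSE1, rose (13 and 2 adjusted over the list alone; median -0.58, adjusted p = 0.00064, adjusted p = 0.33 with an estimated correlation). Of 51 ribosome biogenesis genes 21 rose (22 adjusted over the list alone; median 0.29, adjusted p = 1e-06, adjusted p = 0.33 with an estimated correlation), and of 10 histone genes 4, HTA2, HHT2, HTZ1 and HHO1, rose on the mean of both times (8 adjusted over the list alone; median 0.44, adjusted p = 9e-04, adjusted p = 0.33 with an estimated correlation). That mean joins opposite times in both loops, 1.198 at 40 min (9 rose, 10 adjusted over the list alone; adjusted p = 3.1e-08, adjusted p = 0.11 with an estimated correlation) and -0.22 at 100 min (adjusted p = 0.3). The damage-inducible genes did not pass (RNR2, RNR4, DIN7, DUN1 and PLM2 rose and PHR1 fell, of 19; median -0.01, mean 0.14, adjusted p = 0.35). In total 1977 features passed, 905 higher and 1072 lower, with 1137 without the first loop, 1281 without the second and 267 when the arrays were scaled to equal spread. That scaling ended the calls of MCD1 (1.07, adjusted p = 0.069), POL30 (0.96, adjusted p = 0.12), CDC21 (0.72, adjusted p = 0.099) and CLN2 (0.67, adjusted p = 0.29), and CLN2 also no longer passed without the second loop (0.42, adjusted p = 0.52).

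In galsicΔP cells the samples at 40 min were set against those at 0 min, which are in the first loop only and have n = 2 extracts, to describe the cells between the arrest and the later samples. That loop holds only 1 parent extract at 40 min. The other lies in the second loop and enters the fit only through groups found in both loops. The galactose enzyme genes GAL7 (YBR018C) and GAL1 (YBR020W) rose by 8.52 ± 0.27 and 8.01 ± 0.41 and the galactose permease gene GAL2 (YLR081W) by 6.19 ± 0.31, with 9 of 13 galactose genes higher and 1, GAL4, lower (10 and 1 adjusted over the list alone). The galactose median was 1.27 (adjusted p = 0.00024, adjusted p = 0.21 with an estimated correlation). Of 129 ribosomal protein genes 126 rose and 0 fell (128 adjusted over the list alone; median 4.10, adjusted p = 4.6e-71), and of 27 pheromone response genes 26 fell (26 adjusted over the list alone; median -3.85, adjusted p = 2.4e-21), with the fusion gene FIG1 (YBR040W) at -6.95 ± 0.21. SIC1 rose by 2.99 ± 0.34. NRM1 stood at 2.23 ± 0.28 (adjusted p = 2.4e-07), and at 0.74 (adjusted p = 0.46) when the arrays were scaled to equal spread. Of 43 amino acid genes 33 rose and 5, CPA1, GLN1, SER3, ARG3 and ARG4, fell (the same adjusted over the list alone; median 1.27, adjusted p = 1.7e-07, adjusted p = 0.34 with an estimated correlation), of 51 ribosome biogenesis genes 41 rose and 1, NOP16, fell (the same adjusted over the list alone; median 1.01, adjusted p = 1.7e-08, adjusted p = 0.34 with an estimated correlation) and of 34 proteasome genes 26 fell (27 adjusted over the list alone; median -0.59, adjusted p = 1.6e-05, adjusted p = 0.34 with an estimated correlation). Among the 36 MBF targets 20 rose (20 adjusted over the list alone; median 0.78, adjusted p = 0.0015, adjusted p = 0.6 with an estimated correlation). Of 29 SBF targets 16 rose and 5, PCL2, GIC2, SCW10, TOS1 and NDD1, fell (median 0.80, adjusted p = 0.16). The difference of -0.02 (adjusted p = 0.15) turned to 0.21 (adjusted p = 0.01) with scaled arrays. In total 3583 features passed, 1802 higher and 1781 lower, and 751 with scaled arrays.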

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

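The tests of the arrays in replicate 1, of the untreated samples of replicate 2 and of single 0 min extracts were chosen only after the result was seen, and the other tests before.

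The response of rad53Δ cells differed from that of wild-type cells, by a test of the difference itself, in 175 features for HU and 460 for MMS. For HU, the lists that differed had medians of -0.26 (MBF targets), -0.34 (damage-inducible genes), 0.73 (M/G1 genes), 0.22 (pheromone response genes), -0.44 (stress-induced genes), -0.30 (proteasome genes), -0.24 (oxidative stress genes) and 0.27 (ribosome biogenesis genes). With an estimated correlation the damage-inducible genes still passed (adjusted p = 0.012), and the calls of the others were lost (adjusted p = 0.57, 0.12, 0.27, 0.11, 0.11, 0.16 and 0.27 in this order). For MMS, they were -0.48 (MBF targets), -0.57 (damage-inducible genes), 0.68 (CLB2 cluster), 0.65 (M/G1 genes), 0.27 (pheromone response genes), -0.81 (stress-induced genes), -0.32 (proteasome genes), -0.50 (oxidative stress genes), -0.25 (amino acid genes), 0.61 (ribosome biogenesis genes) and -0.08 (galactose genes). With an estimated correlation 4 of these still passed, the damage-inducible (adjusted p = 0.0022), stress-induced (0.0064), oxidative stress (0.011) and ribosome biogenesis genes (0.019). Those lost were MBF targets (0.23), the CLB2 cluster (0.2), M/G1 genes (0.2), pheromone response genes (0.23), proteasome genes (0.12), amino acid genes (0.23) and galactose genes (0.31).

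Label exchanges within blocks were counted for each comparison, the real labels among them. For HU in wild type 1 of 100 gave as many features, the real one with 2067 against at most 1850 in the others, so chance can be excluded for exchanges within blocks taken as independent. That highest one exchanges HU and untreated in 7 of 8 blocks and is close to the real contrast with its sign turned. For MMS 1 of 100 did (3634, highest other 3273) and for MMS against HU 1 of 100 (2572, highest other 2111), so chance can be excluded there with the same limit. The 8 blocks are 4 times of only 2 replicates, and exchanges of whole replicates are too few for a share under 0.05. With 1 value per replicate and treatment the counts were 843, 2515 and 1229. For CPT 5 of 100 gave as many, with 376 for the real labels and 1236 at most, so chance cannot be excluded. That highest value, several times the real count, came from exchanging the 45 and 75 min blocks of replicate 2, and its cause was not tested. The other comparisons allow too few exchanges for a share under 0.05: rad53Δ HU with 447 against at most 297 among 8 (1 as large), rad53Δ MMS with 836 against 285 among 8 (1), nrm1Δ with 1977 against 685 among 8 (1), and the differences between strains with 175 against 121 (1) and 460 against 201 (1) among 18.

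In wild-type replicate 2 the responses of cell cycle genes at 30 and 45 min followed those of replicate 1 poorly. Without these samples the difference between strains in MBF targets turned from -0.26 to 0.09 for HU (adjusted p = 0.98), and for MMS it went from -0.48 to -0.17 and still passed. For MMS the CLB2 cluster, at 0.32 in replicate 1 and 1.07 in replicate 2, went from 0.68 to 0.39 and still passed, and the galactose genes no longer did (adjusted p = 0.05). Pheromone response genes stood at 0.45 and -0.005 in the replicates for HU and at 0.46 and 0.095 for MMS. Over 115 cell cycle genes the correlation with replicate 1 rose when its responses were computed against the untreated sample of the other time, by 0.474 at 30 min, the smaller gain, and 0.558 at 45 min, which is consistent with an exchange of these untreated RNAs. An exchange of all RNA on these slides is argued against, since r was lower by 0.441 at 45 min than with the untreated RNA alone exchanged (difference -0.441). Faster or slower untreated cells are argued against too, because the best-matching times lie on opposite sides (product of the shifts -225). What stays open is whether the exchange took place, and a biological difference between replicates was not tested.

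In wild-type replicate 1 the log ratios around the untreated and CPT loops summed further from 0 than those of the other loops (SD 0.943 and 0.721, against 0.528 for MMS and 0.377 for HU). The untreated loop lies on slides 3 and 4, and the CPT loop shares slide 3 with it. Their sums, each less the MMS sum, correlated across genes at r = 0.889, against 0.246 from the shared MMS sum alone, which may reflect a dye bias of slide 3. For slide 4, the HU loop had the smallest SD of the 4, which goes against a large bias there, though with 1 array of that slide it excludes none. A different 0 min RNA, the same on slides 3 and 4, is argued against for the untreated loop, whose sum had 1.79 times the SD of the MMS loop although both of its 0 min arrays lie on them. A separate dye term for slides 3 and 4 moved none of the counts of features by more than 1.5 times, and no biological explanation was tested.

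The ribosomal protein genes of galsicΔP cells stood 4.10 higher at 40 min than at 0 min. A rise of abundant transcripts in general is argued against, since 20 abundant non-ribosomal transcripts had a median of 0.281. A single deviant 0 min extract is argued against as well, since the lower of the medians against each extract was 4.021 and the other 4.181. Both medians use the same 40 min extract, so a deviant extract at 40 min is not covered. A biological change between arrest and release, which the design names as time, is a hypothesis that stays open, beside any effect of the unknown normalisation. Galactose genes rose between the same samples. Time after the arrest and whatever change raised these genes cannot be told apart here.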

How the results depend on the processing

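The alternatives chosen only after seeing the data are those without the 30 and 45 min blocks of wild-type replicate 2, with 60 and 75 min only, with 75 min only, with a separate dye term for slides 3 and 4, and with 1 value per replicate and treatment. Keeping features with missing values was not run, since there were 0. Of the values for gene lists, 1879 stayed on their side of the threshold with their direction, 154 no longer passed, 44 newly passed and 83 turned. For named genes these numbers were 2609, 216, 29 and 8. Of the counts of features 88 stayed within 1.5 times and 36 did not, of the MBF against SBF values 98 stayed, 15 no longer passed, 11 newly passed and 10 turned, and of the untreated time course 272 stayed and 8 moved. Of the values that turned, 71 of lists, 7 of named genes and 8 of MBF against SBF passed neither before nor after, so neither fit gave them a direction. Where no cause is named, the cause was not tested. Signal over background was not used here, so its limit on weak transcripts is unknown.

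The array-level fits change the unit of the fit and the replicate block together, so their moves cannot be put down to either. With no replicate block, the array-level fit gave 1166 features for rad53Δ HU, 1514 for rad53Δ MMS, and 674 (HU) and 832 (MMS) for the difference between strains. MBF against SBF was 0.061 for MMS against HU (adjusted p = 0.084) and 0.082 for rad53Δ HU (adjusted p = 0.019). With slide as a random term, correlation 0.056, these were 1142, 1662, 708, 914, 0.066 (adjusted p = 0.13) and 0.077 (adjusted p = 0.021). MBF against SBF turned in these 2 fits for nrm1Δ (-0.228 and -0.194, from 0.08) and galsicΔP over time (0.005 and 0.002). Lists that turned in both were SBF targets in HU (-0.055 and -0.06), pheromone genes in HU (0.056 and 0.057) and CPT (0.04 in each), histone genes in rad53Δ MMS (0.016 and 0.019), SBF targets (0.04 in each) and histone genes (0.013 and 0.023) for the difference in MMS, and the CLB2 cluster for nrm1Δ (0.011 in each). In the first alone galactose genes in MMS against HU turned (0.001), and in the second the other mating type in CPT (-0.006), ribosomal protein genes for the difference in MMS (0.001) and damage-inducible genes for nrm1Δ (0.004).

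With arrays centred and scaled, the difference between strains gave 98 features for HU and 149 for MMS, nrm1Δ 267 (78 higher and 189 lower, 29.2% against 45.8% higher before) and galsicΔP over time 751 (475 and 276, 63.2% against 50.3%). MBF against SBF was 0.15 for MMS against HU (adjusted p = 0.068), 0.11 for rad53Δ HU (adjusted p = 0.014) and turned to 0.21 for galsicΔP over time (adjusted p = 0.01). For nrm1Δ it turned to -0.108. The pheromone list in rad53Δ MMS turned to 0.028 and in CPT to 0.106, SBF targets to -0.005 in HU and -0.067 in rad53Δ MMS, galactose genes in MMS against HU to 0.02, and the other mating type for the difference in MMS to 0.007. For the difference in HU histone genes turned to -0.002 and ribosomal protein genes to 0, and for galsicΔP over time histone genes to -0.248, M/G1 genes to -0.046 and stress-induced genes to 0.211. With arrays only centred, ribosomal protein genes for the difference in HU turned to 0.003. A fit per strain set gave 59 features for CPT, 2003 for rad53Δ HU and 2396 for rad53Δ MMS, as each set then has its own spread, and MBF against SBF of 0.023 for rad53Δ HU (adjusted p = 0.031), 0.08 for nrm1Δ (adjusted p = 7.5e-05) and -0.024 for galsicΔP over time (adjusted p = 0.014). Without the array of conflicting times MBF against SBF for rad53Δ HU was 0.036 (adjusted p = 0.043), and the other mating type in rad53Δ MMS turned to -0.059.

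Leaving out each replicate in turn, where a lone sample is assumed to vary like the other groups, gave 110 to 1976 features for CPT, 34 to 43 for rad53Δ HU, 168 to 203 for rad53Δ MMS, 16 to 256 and 45 to 631 for the differences between strains in HU and MMS, and 1137 to 1281 for nrm1Δ. MBF against SBF ran from 0.039 to 0.275 for MMS against HU, 0.089 to 0.158 for rad53Δ HU, -0.44 to -0.18 for the difference in HU and -0.45 to 0.42 for nrm1Δ, the lower value turned. Ribosome biogenesis genes in CPT ran from -0.236 to 0.088, turned without wild-type replicate 2, and MBF targets for the difference in HU from -0.513 to 0.007, turned likewise. The further ranges that cross 0 are those of MBF against SBF in rad53Δ MMS (-0.021 to 0.094) and of lists that did not pass with all replicates, though some passed on one side. In HU they were SBF targets (-0.004 to 0.089), pheromone (-0.194 to 0.12), amino acid (-0.014 to 0.138) and galactose genes (-0.009 to 0.046), in MMS galactose (-0.037 to 0.08) and histone genes (-0.412 to 0.071), and in CPT pheromone genes (-0.132 to 0.077), the other mating type (-0.08 to 0.394) and SBF targets (-0.138 to 0.054), while histone genes stayed below 0 (-0.187 to -0.005). In rad53Δ MMS they were histone genes (-0.2 to 0.108) and the other mating type (-0.063 to 0.013). For the difference in HU they were SBF targets (-0.07 to 0.19), the other mating type (-0.15 to 0.123), ribosomal protein genes (-0.074 to 0.056) and the CLB2 cluster (-0.023 to 0.682), and in MMS ribosomal protein genes (-0.164 to 0.054), SBF targets (-0.234 to 0.243) and the other mating type (-0.219 to 0.024). For nrm1Δ they were the CLB2 cluster (-0.146 to 0.009), ribosomal protein genes (-0.13 to 0.01) and damage-inducible genes (-0.049 to 0.058), and M/G1 genes for galsicΔP over time turned to -0.147. Of named genes without a call, RNR1 in rad53Δ MMS ran from -1.339 to 0.04, HUG1 in rad53Δ HU from -0.06 to 0.296, RAD53 there from -0.117 to 0.011, and in HU CLN1 from -0.49 to 0.307 and PCL1 from -0.434 to 0.217.

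With the correlation estimated, 20 of 150 list shifts passed in place of 96, and MBF against SBF no longer passed for HU (0.47, adjusted p = 0.2), MMS (0.47, adjusted p = 0.21), CPT (0.27, adjusted p = 0.32), MMS against HU (0.17, adjusted p = 0.68) or the differences between strains (-0.31 and -0.48, adjusted p = 0.32 each).

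Without the 30 and 45 min blocks of wild-type replicate 2, the differences between strains gave 109 (HU) and 283 (MMS), MBF against SBF for HU there -0.18 (adjusted p = 0.095), SBF targets newly passed there (0.264, adjusted p = 0.042), MBF targets turned to 0.088 and ribosome biogenesis genes in CPT to 0.027. Without a call before or after, galactose genes in HU turned to -0.013, histone genes in CPT to 0.036, the CLB2 cluster and the other mating type for the difference in HU to -0.096 and 0.006, SBF targets for that in MMS to 0.198, and CLN1 and PCL1 in HU to 0.03 and 0.108. With 60 and 75 min only, MBF against SBF for MMS against HU was 0.038 (adjusted p = 0.097), and histone genes turned to 0.60 in HU, 0.63 in MMS and 0.005 in CPT, galactose genes in MMS against HU to 0, the CLB2 cluster in CPT to 0.04 and HSP12 in MMS against HU to 0.046. With 75 min only, rad53Δ HU gave 1021 and the difference for HU 503 features, MBF against SBF in the differences was -0.48 (adjusted p = 0.27) and -0.24 (adjusted p = 0.11), MBF targets turned to 0.272 and 0.033, histone genes in rad53Δ MMS to 0.43 and the CLB2 cluster in the difference for HU to -0.40. MBF against SBF turned to -0.114 in rad53Δ HU and -0.034 in rad53Δ MMS, galactose genes in rad53Δ MMS to 0.016, and in the difference for HU histone genes to -0.257, the other mating type to 0.22 and ribosomal protein genes to 0.058, with SBF targets for MMS at 0.271. A separate dye term turned SBF targets in HU to -0.019 and in CPT to 0.039, amino acid genes in CPT to 0.008 and ribosomal protein genes for the difference in HU to 0.002. With 1 value per replicate and treatment, which leaves fewer samples, counts were 843 for HU, 5 for CPT, 1229 for MMS against HU, and 54 and 294 for the differences, and MBF against SBF was 0.023 for rad53Δ HU (adjusted p = 0.0047) and 0.08 for nrm1Δ (adjusted p = 0.0018).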

Other observations

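The tests across MBF members below were chosen before the result was seen. The group of mitochondrial genes was chosen after its values were seen and was not tested as a list.

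Features encoded in the mitochondrial genome, 19 in all, had a median of -1.26 in wild-type MMS with 16 lower. Against this stood -0.35 in HU with 1 lower and -0.52 in CPT with 6 lower. The smallest changes in wild-type MMS were those of OLI1 at -0.23 and ATP6 at -0.33. The 19 features are not independent of one another, so their counts are not counts of separate transcripts. In MMS against HU their median was -0.91, with 17 lower. In rad53Δ cells the median was -0.96 in MMS with 8 lower, and the difference to wild type was 0.13, with 0 passing in limma. COX1, the gene of a cytochrome oxidase subunit, stood at -2.07 ± 0.20 in wild-type MMS, and in CPT the apocytochrome b gene COB (Q0105) stood at -1.15 ± 0.26 and the ribosomal protein gene VAR1 (Q0140) at -1.20 ± 0.32. In galsicΔP cells 13 of the 19 were lower at 40 min than at 0 min (median -1.24), and 3 were higher in nrm1Δ (median 0.33).

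In rad53Δ cells the acid phosphatase gene PHO3 (YBR092C) stood at -1.88 ± 0.17 in HU and -2.14 ± 0.17 in MMS, and PHO12 (YHR215W) at -1.66 ± 0.19 and -1.99 ± 0.19. PHO5 (YBR093C), at 0.12 ± 0.17 and -0.42 ± 0.17, passed with neither agent, and its MMS response was 1.55 ± 0.23 higher than in wild type (adjusted p = 0.00016). The fatty acid desaturase gene OLE1 (YGL055W) stood at -1.12 ± 0.20 and -1.53 ± 0.20, and the membrane protein gene MRH1 (YDR033W) at -2.08 ± 0.27 and -1.94 ± 0.27. The difference between strains for HU was -1.57 ± 0.26 for PHO12 (adjusted p = 0.0012) and -1.48 ± 0.38 for MRH1 (adjusted p = 0.035), while REC104 (YHR157W) was higher by 1.54 ± 0.12 (adjusted p = 2.2e-08).

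A hypothesis set before the test was that the MBF targets most raised by loss of Nrm1 are those most raised by replication stress. Across the 36 members, which are not independent of one another, the nrm1Δ effect and the wild-type HU effect had Spearman's rho = 0.443 (Pearson's r = 0.416, permutation p = 0.0073, adjusted p = 0.011 over the family of 3). For MMS rho was 0.525 (r = 0.539, permutation p = 0.0011, adjusted p = 0.0033), which is consistent with the hypothesis, since no array is shared between these strains. For MMS in rad53Δ cells rho was 0.097 (r = 0.0765, permutation p = 0.57, adjusted p = 0.57), which leaves it open there, and the difference between these correlations was not tested. The values could also follow from how strongly each member cycles, which was not tested.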
